A study of Drosophila melanogaster with 6 samples.

How the data were processed

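Chromatin of Drosophila S2 cells was digested with micrococcal nuclease (MNase), which cuts DNA that is not covered by protein, and the protected DNA was sequenced from both ends. The S2 line grows in culture and was derived from embryos. The labels describe 6 libraries with 1 sample per group. S2_total held all DNA from digested nuclei, and S2_short held a short-fragment library of such DNA. The other 4 libraries (dsGFP, dsSpt16, dsSSRP and dsSpt6) held chromatin soluble in a low-salt buffer, 80 mM per the labels, from cells given double-stranded RNA. The dsRNA against GFP, a jellyfish protein that flies lack, served as the control. The labels name the cells of the low-salt libraries S2 DRSC and those of the other libraries S2, so salt extraction and cell stock could not be separated between these sets, and no comparison between them was planned.

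Each sample came with 2 files, which the labels call technical replicates. The files of a sample were treated as 2 runs of 1 sample and pooled. A difference between groups therefore had no replicate check, no p-value was computed, and the difference between runs was used as technical spread. The titles of S2_total and S2_short each carry a 2014 and a 2016 date, without tying a date to a run. Runs of these libraries may therefore differ by more than sequencing. Run numbers only name the runs. Intervals and floors cover counting error only, since sequenced fragments without molecular identifiers are not independent molecules.

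The deposited files list 1 sequenced fragment per line with its chromosome, start and end, and hold no counts or signal of their own. Novoalign 2.08.03 is named in the submitters' processing notes. The genome build, the alignment filters and the treatment of duplicates are not given in the sources used here. Sequence names (2L, 2R, 3L, 3R, X, 4, 6 heterochromatic sequences ending in Het, and the unplaced sequence U) and the highest ends match Release 5 of the Drosophila genome, and all coordinates are on that build as the files give them. The gene table used with these files was of Release 6. None of its coordinates were printed, no gene was assigned to a position, and the gene lists fixed in advance were not used. No mitochondrial sequence was listed, so the planned mitochondrial background was not used either.

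Fragment length was taken as end minus start. The lowest start in any file was 1, so the start may be counted from 1 and a length may be 1 bp too short. In both S2 libraries the ends in run 1 lay 1 bp further than in run 2. On the first 6 Mb of 2L, 18.2% of distinct S2_short run 1 fragments had a run 2 fragment with the same start and a length 1 bp shorter, against 7.73% with the same length. The 2 values for S2_total were 3.17% and 0.891%. In the low-salt libraries the same-length match was the most frequent, with 6.82% in dsGFP.

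Fragments were divided into short (20 to under 80 bp), hexasome-sized (80 to under 120 bp), partly unwrapped (120 to under 140 bp), nucleosome-sized (140 to under 170 bp), linker-carrying (170 to under 230 bp) and long (230 bp and over). A nucleosome wraps DNA around 8 histones, and a hexasome has lost 1 of the 2 pairs of H2A and H2B. The hexasome-sized share is the percentage of hexasome-sized fragments among hexasome-sized plus nucleosome-sized fragments. Percentages of length classes refer to fragments on the 6 euchromatic arms (2L, 2R, 3L, 3R, X and 4) and carry 95% Wilson intervals in the results tables.

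Promoter-like sites were defined from the S2 libraries alone. They are local maxima of short S2_short midpoints, smoothed with an SD of 30 bp, at least 10 times the arm mean and 500 bp apart. The nucleosome-sized S2_total density within 50 bp of the site had to lie under that at 100 to 400 bp by a factor of at least 2. Of 2236 maxima, 552 passed. The strand of transcription is unknown, so profiles were folded around each site. The nearest nucleosome on either flank was the highest nucleosome-sized S2_total density 60 to 260 bp from the site, smoothed with an SD of 20 bp. It was found on 1014 of 1104 flanks, at a median distance of 157 bp. Midpoints 10 to 60 bp from the dyad, the middle of the nucleosomal DNA, were counted on the site-distal and site-proximal sides. Control windows were 5000 nucleosomes at least 3000 bp from any site.

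Change at a site was the log2 ratio of fragments within 500 bp, scaled to all main-arm fragments of each library, and the difference of the hexasome-sized share, for sites with at least 50 fragments of 80 to under 170 bp in both libraries. Intervals of medians came from 1000 bootstrap draws of sites and describe these libraries, not the conditions. The rule for named sites was fixed before the data were examined: per knockdown and measure, the 5 highest and 5 lowest sites with the same sign in both runs. Correlations between knockdowns share the dsGFP library, so 200 simulated Poisson pairs without change were set beside them. Windows of 1 kb that hold the most fragments, the 10 leading windows of each library, were listed after the data were seen, as were the zones in which densities around sites were compared (within 50 bp and 100 to 200 bp).

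Site calling, dyad calling, side counts and fold changes were tested on simulated data. Of 300 planted sites, 300 were found within 50 bp, with a median dyad error of 3 bp. A planted site-distal share of 60% was measured as 60.05%. Those midpoints were planted around the called dyads, so this checks only the counting of sides and not the effect of dyad error. A planted log2 fold change of 0.58 was measured as 0.58, with -0.03 at unchanged sites. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, pyarrow 21.0.0 and Matplotlib 3.10.9. Alternatives planned in advance were each run alone, identical fragments counted once, narrower length classes (90 to under 110 and 140 to under 160 bp), all sequences, dyads from the low-salt libraries, midpoints 10 to 40 bp from the dyad, a minimum of 100 fragments or none, thinning to the shallowest library, median scaling, and dsGFP reweighted to the length distribution of a knockdown.
Shares per sequence were also set against dsGFP reweighted to the main-arm lengths of a knockdown, without the 14 leading windows, a comparison added after the data were seen.
Further alternatives were chosen after the data were seen: sites at least 4 times the arm mean, leaving out the 1% or 10% of sites with the most fragments, scaling to all sequences, scaling densities around sites to all main-arm fragments instead of those of the same class, S2 run 1 ends shortened by 1 bp, reweighted dsGFP for the regional ratios, and leaving out the X window or the 9 leading windows outside the main arms.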

Results

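MNase digestion of S2 chromatin was sequenced to map subnucleosomal particles, such as those that a polymerase could leave when it passes a nucleosome. S2_total and S2_short came from digested nuclei, and dsGFP, dsSpt16, dsSSRP and dsSpt6 from low-salt soluble chromatin of cells given double-stranded RNA. Spt16 and SSRP are the subunits of FACT, a histone chaperone that removes and returns H2A and H2B during transcription. Spt6 is a histone chaperone that travels with elongating polymerase and binds H3 and H4. Each group had 1 sample sequenced in 2 technical runs, so no difference between groups has a replicate check. S2_total held 58486294 fragments (10138075 and 48348219 per run), S2_short 124200913 (18086896 and 106114017), dsGFP 26819033, dsSpt16 26418617, dsSSRP 26483305 and dsSpt6 28234290. MNase DNA does not measure the targeted transcripts, so the extent of each knockdown was not analysed here.

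The short-fragment library was set against the total digest to ask which particles smaller than a nucleosome it holds. In S2_short, 69.5% of main-arm fragments were hexasome-sized, against 8.03% in S2_total, and 29.5% were short, against 3.6%. Nucleosome-sized fragments made up 24.8% of S2_total and 0.479% of S2_short. Run 1 and run 2 gave 71.9% and 69.1% hexasome-sized fragments in S2_short, and 7.78% and 8.08% in S2_total, so the libraries differed by far more than their runs. S2_short is a short-fragment library by its title. Its excess of lengths below a nucleosome therefore follows from its preparation and is no result about the chromatin. The most frequent length in S2_short was 90 bp in run 1 and 89 bp in run 2, with further peaks at 79 and 69 bp in run 1 and at 78 and 68 bp in run 2. S2_total had local peaks at 57, 68, 78, 89, 101 and 109 bp in run 2.

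The most frequent S2_total length differed between runs, 172 bp in run 1 and 150 bp in run 2, and a single segment of X set this difference. The 1 kb window X 21834001 to 21835000 held 3.93% of all S2_total fragments in run 1 and 5.56% in run 2, most of them between 21834850 and 21835027. In run 1, 65.1% of the fragments in this window were linker-carrying, while in run 2, 71.6% were nucleosome-sized. Without this window the most frequent lengths were 152 and 151 bp, and nucleosome-sized fragments made up 21.6% and 22.0% of the runs. The window held 0.800% of S2_short fragments and 0.631% of dsGFP fragments. This window was singled out after the data were seen, and no gene or repeat annotation was used for it.

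**Figure D1:**
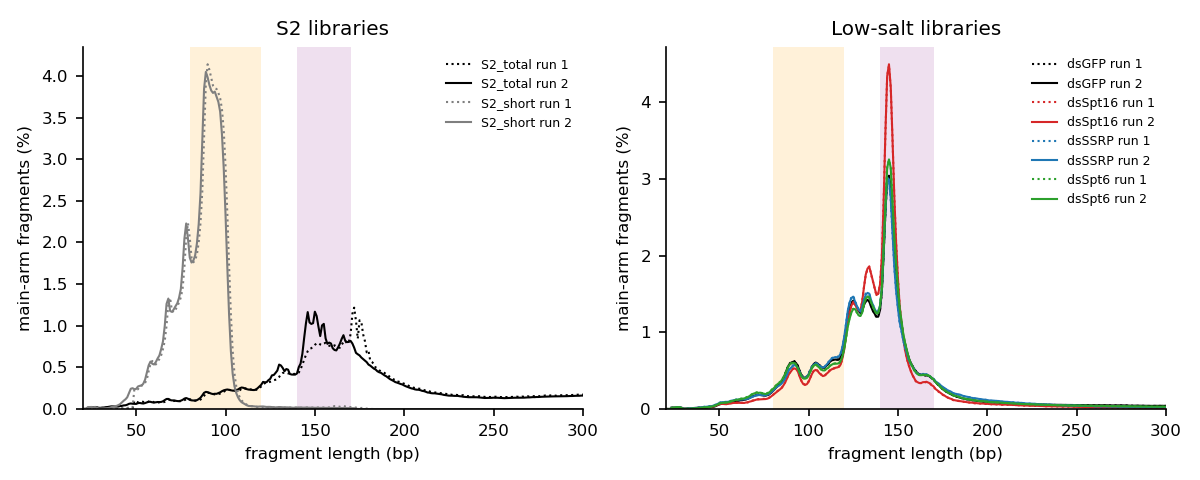
Percentage of main-arm fragments (vertical axis) by fragment length in bp (horizontal axis), left for the S2 libraries and right for the low-salt libraries; dotted lines are run 1, solid lines run 2, and shading marks the hexasome-sized and nucleosome-sized ranges. S2_short peaks at 90 and 89 bp, the S2_total runs part between 140 and 180 bp, and dsSpt16 has the highest peak at 145 bp.

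The knockdown libraries were compared with dsGFP to ask how loss of FACT or Spt6 alters the particles released at low salt. The dsSpt16 library held fewer hexasome-sized and more nucleosome-sized fragments, 17.1% and 43.2% of main-arm fragments, against 20.9% and 35.6% in dsGFP. The dsSSRP library, from cells targeted for the other FACT subunit, did not show this shift, with 20.6% hexasome-sized and 34.7% nucleosome-sized fragments. The dsSpt6 library held 20.1% hexasome-sized and 37.4% nucleosome-sized fragments. Long fragments were fewer in every knockdown, 2.10% in dsSpt16, 4.07% in dsSSRP and 4.64% in dsSpt6 against 5.93% in dsGFP.

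Expressed as the hexasome-sized share over the main arms, dsGFP stood at 36.9%, dsSpt16 at 28.4%, dsSSRP at 37.3% and dsSpt6 at 34.9%. The dsSpt16 difference of -8.56 percentage points, the dsSSRP difference of 0.39 and the dsSpt6 difference of -2.0 each exceeded the difference between runs of a library, in dsSSRP by little. The dsSSRP value was smaller with narrower length classes and turned to -1.81 when all sequences were counted. Within heterochromatic and unplaced sequence it was -4.74, a drop that was smaller with identical fragments counted once. All 4 low-salt libraries peaked at 144 or 145 bp and shared local peaks at 104 and 125 bp. In dsSpt16 the nucleosome-sized excess of 7.58 points was the same within 0.1 points in run 1 and run 2.

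The drop of the hexasome-sized share in dsSpt16 extended over every sequence. It was -9.11 points on 2L, -8.59 on 2R, -8.73 on 3L, -8.86 on 3R, -6.66 on X and -8.33 on chromosome 4, and -11.1 on U. In dsSSRP the arms 2L, 2R, 3L and 3R changed by 0.19 to 0.80 points, whereas chromosome 4, a small chromosome rich in heterochromatin proteins, changed by -2.16 and U by -5.23. In dsSpt6 the arms 2L to 3R changed by -1.92 to -2.16 points and U by -5.03. Chromosome 4 had the highest hexasome-sized share of the main arms in each low-salt library, 45.4% in dsGFP, 37.1% in dsSpt16, 43.3% in dsSSRP and 43.3% in dsSpt6.

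Heterochromatic and unplaced sequence took a larger part of each knockdown library. It held 26.7% of dsGFP fragments, 33.3% of dsSpt16, 34.9% of dsSSRP and 31.5% of dsSpt6 fragments, which are ratios of 1.25, 1.31 and 1.18 to dsGFP. The unplaced sequence U rose from 17.1% to 23.3%, 23.6% and 21.0%, and YHet from 0.321% to 0.553%, 0.524% and 0.430%. In dsSpt16 the rise lay mostly in U, since all Het sequences together had a ratio of 1.04, with 0.978 for 2RHet and 0.974 for 3LHet. There the median log2 ratio was -0.23 over the 7863 of 9285 Het windows of 1 kb that passed a minimum of 50 fragments, and 22.6% of those were above 0. Main-arm windows under the same minimum were close to this, with a median of -0.25 and 21.2% above 0. In dsSSRP and dsSpt6 the Het sequences together had ratios of 1.17 and 1.08. Within the main arms, the share of chromosome 4 relative to dsGFP was 0.888 in dsSpt16, 1.11 in dsSSRP and 1.02 in dsSpt6. Per run the chromosome 4 ratio was 0.881 and 0.893 in dsSpt16.

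The 9 windows of 1 kb outside the main arms among the 10 with the most fragments in dsGFP were examined for this gain. They were chosen from dsGFP alone, after the data were seen, and lie on U (first bases 1941001, 10033001, 7934001, 5528001, 2769001, 8609001, 9151001 and 9599001) and 3RHet (2308001). In each knockdown 8 of them were higher than in dsGFP, and U 9151001 was lower. Together they held 3.92% of dsGFP fragments, 7.33% of dsSpt16, 6.93% of dsSSRP and 6.19% of dsSpt6 fragments, with median ratios to dsGFP of 1.94, 1.87 and 1.6. In dsGFP 57.5% of their fragments were nucleosome-sized and 35.5% partly unwrapped, and their hexasome-sized share was 7.39%, against 3.01% in dsSpt16, 6.0% in dsSSRP and 4.9% in dsSpt6. These windows made up 51.8%, 36.7% and 47.8% of the gain in dsSpt16, dsSSRP and dsSpt6. Without them the ratios of heterochromatic and unplaced sequence were 1.18, 1.27 and 1.14.

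**Figure D2:**
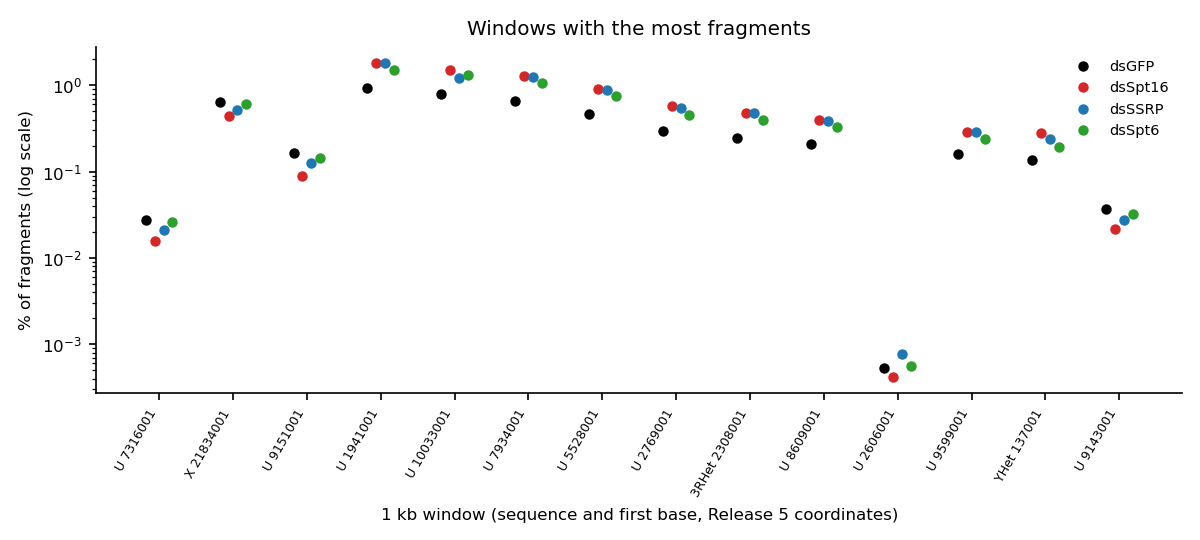
Percentage of all fragments (vertical axis, log scale) in the 14 windows of 1 kb that were among the 10 leading windows of any library (horizontal axis: sequence and first base), 1 point per low-salt library. U 1941001 holds 0.929% of dsGFP and 1.82% of dsSpt16 fragments, while the X window and U 9151001 lie lower in every knockdown than in dsGFP.

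**Figure D3:**
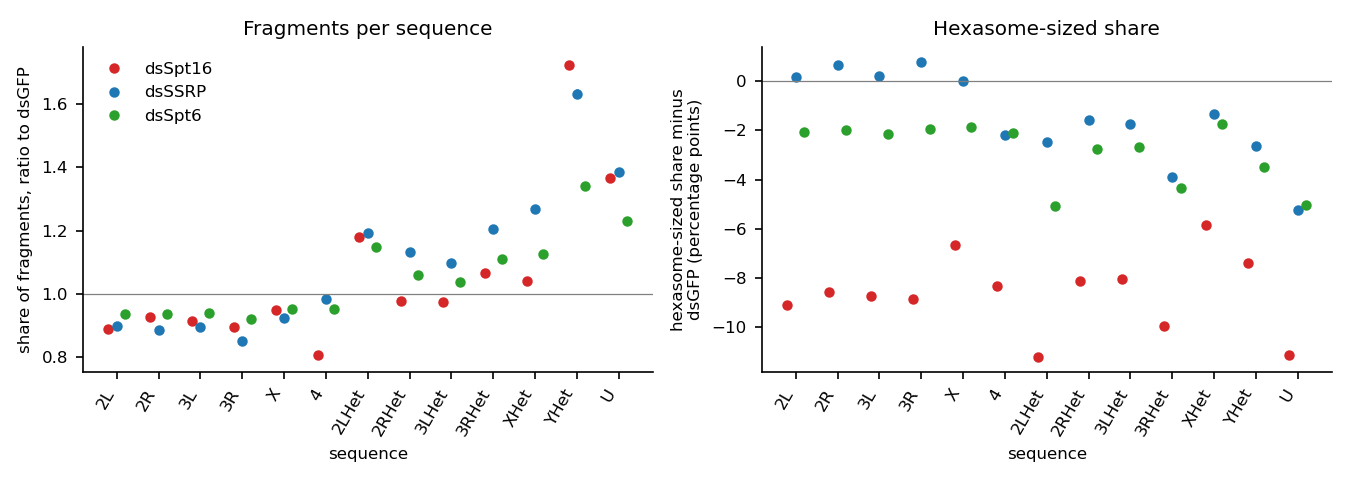
Left, ratio of the share of fragments on each sequence to that in dsGFP; right, hexasome-sized share minus that in dsGFP in percentage points; points are pooled values and vertical lines in the left panel, mostly hidden by the points, span the runs. YHet and U lie highest on the left, and dsSpt16 lies below the other knockdowns for every sequence on the right.

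Of the other leading windows, X 21834001, U 7316001 and U 9143001 were lower in every knockdown, as was U 9151001. U 9151001 to 9152000 held 0.166% of dsGFP fragments, 0.0890% of dsSpt16, 0.124% of dsSSRP and 0.143% of dsSpt6 fragments. U 7316001 to 7317000 stood at 0.0276% in dsGFP and 0.0156% in dsSpt16, and the X window at 0.631% and 0.443%. The ratios to dsGFP at U 9143001 were 0.576 in dsSpt16, 0.736 in dsSSRP and 0.865 in dsSpt6. YHet 137001 was instead higher in every knockdown, with ratios of 2.1, 1.78 and 1.44, and U 2606001 was lower in dsSpt16 (0.783) but not in dsSSRP (1.45) or dsSpt6 (1.06).

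Promoter-like sites, 552 places with a peak of short fragments inside a nucleosome-depleted gap, were used to ask where the particles lie around open regulatory DNA. In the low-salt libraries, which played no part in choosing the sites, hexasome-sized fragments were depleted at the site itself, with 0.670 times the main-arm mean in dsGFP, and enriched 2.21 times at 100 to 200 bp, where the first nucleosome lies. In the S2 libraries hexasome-sized fragments were instead enriched within 50 bp, 4.31 times in S2_total and 7.80 times in S2_short, more than at the first nucleosome (2.89 and 3.18 times). Short S2_short fragments stood at 18.4 times there, and nucleosome-sized S2_total fragments at 0.416 times there and 1.78 times at 100 to 200 bp. These 3 values follow from the selection, which required a short S2_short peak and an S2_total gap. The hexasome-sized S2 values at the site are not free of that selection either, since the peaks were called in S2_short. Sites at least 4 times the arm mean were added after the data were seen. With them, hexasome-sized density was 2.36 at the site and 2.13 at the first nucleosome in S2_total, and 4.0 and 2.16 in S2_short.

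Both FACT knockdowns had more short fragments at the sites. Their density relative to the main-arm mean of short fragments was 7.58 in dsGFP, 15.8 in dsSpt16, 12.1 in dsSSRP and 8.82 in dsSpt6. The ratio to dsGFP was 2.1 in dsSpt16 (site bootstrap 1.80 to 2.63), 1.59 in dsSSRP (1.44 to 1.87) and 1.16 in dsSpt6 (0.85 to 1.30). In dsSpt16, 290 of 481 sites with such fragments were higher and 191 lower, and in dsSSRP 354 of 507 were higher. In dsSpt6, 296 of 489 were lower. With sites at least 4 times the arm mean, a threshold added after the data were seen, the ratios were 1.6, 1.5 and 0.973. Scaled to all main-arm fragments instead of short ones, also added afterwards, they were 1.68, 1.78 and 1.36, so the order of the FACT knockdowns depends on the scaling.

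Density at the first nucleosome beside the site depended on how libraries were scaled. Relative to main-arm fragments of the same class, nucleosome-sized density was 1.38 times that of dsGFP in dsSSRP (1.30 to 1.46), 1.12 times in dsSpt16 (1.054 to 1.19) and 0.959 times in dsSpt6 (0.916 to 0.999). Hexasome-sized density was 1.25 times in dsSSRP, 1.17 times in dsSpt16 and 1.07 times in dsSpt6. Scaled to all main-arm fragments, an alternative added after the data were seen, the nucleosome-sized ratios were 1.36 in dsSpt16 (1.28 to 1.44), 1.35 in dsSSRP (1.26 to 1.42) and 1.01 in dsSpt6, and the hexasome-sized ratios 0.960, 1.24 and 1.03. With scaling by class, in dsSSRP 342 of 549 sites were higher, but in dsSpt16 246 were higher and 303 lower. These zones were chosen after the profiles were seen. Without the 10% of sites with the most fragments, also added afterwards, the nucleosome-sized ratio by class was 1.21 in dsSSRP, 0.972 in dsSpt16 and 0.872 in dsSpt6.

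**Figure D4:**
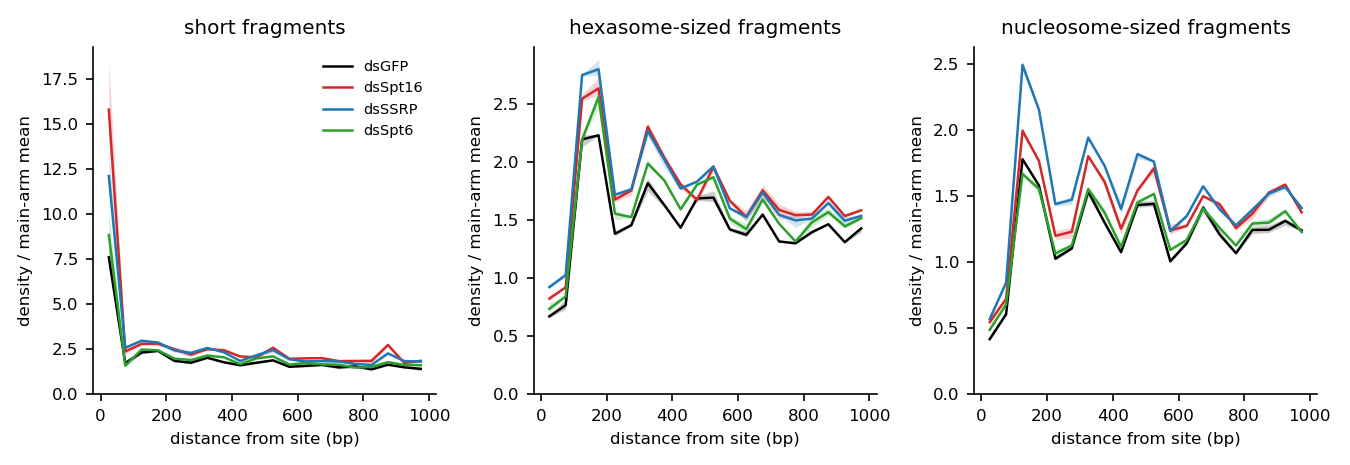
Fragment density relative to the main-arm mean of the same length class (vertical axis) by distance from 552 promoter-like sites in bp (horizontal axis, both flanks folded), for short, hexasome-sized and nucleosome-sized fragments; lines are pooled values and shading spans the runs. Short fragments at the site reach 15.8 in dsSpt16 and 12.1 in dsSSRP against 7.58 in dsGFP, and nucleosome-sized fragments at the first nucleosome are highest in dsSSRP on this scale by class.

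The amount of low-salt soluble DNA was compared over the whole 1 kb around a site. The median log2 ratio to dsGFP was -0.03 in dsSpt16 (-0.07 to 0.03, 466 sites), 0.11 in dsSSRP (0.07 to 0.14, 473 sites) and -0.07 in dsSpt6 (-0.10 to -0.04, 476 sites). Control windows had medians of -0.13, -0.11 and -0.06, so sites lay above controls in dsSpt16 and dsSSRP and near them in dsSpt6. In dsSSRP 310 sites were higher and 163 lower. In dsSpt16 226 were higher and 240 lower, and in dsSpt6 174 were higher and 302 lower. Scaled to the median ratio the medians are 0 by construction. Scaled to all sequences instead of the main arms, an alternative added after the data were seen, the dsSSRP median was -0.06, so its direction depends on the denominator. With a minimum of 100 fragments the dsSpt16 median was 0.13. The 2 runs of dsGFP differed at single sites with an SD of 0.26 on the log2 scale. The change had an SD of 0.35 in dsSpt16, 0.31 in dsSSRP and 0.22 in dsSpt6. These SDs are not directly comparable, since the first sets single runs against each other and the others pooled libraries, which hold more fragments.

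The hexasome-sized share at promoter-like sites fell in dsSpt16 as it did elsewhere. Its median was 46.7% in dsGFP and 37.5% in dsSpt16, with a median difference of -7.61 points (-8.35 to -6.66), and 381 sites were lower and 84 higher. At control windows the median difference was -7.90 points. In dsSSRP the median difference was -0.23 points (-1.09 to 0.82) and in dsSpt6 0.57 points (-0.28 to 1.40), neither distinguishable from 0, while control windows in dsSpt6 changed by -1.75 points. Against dsGFP reweighted to the fragment lengths of the knockdown, the dsSpt16 difference was 1.73 points and the dsSpt6 difference 2.50 points.

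Changes in the 3 knockdowns were compared across sites, all against the same dsGFP library. The log2 changes of dsSpt16 and dsSSRP had a Pearson r of 0.44 over 455 sites, which are not independent replicates, but unchanged libraries that share dsGFP gave 0.48 by simulation. The covariance was 0.0473 against a simulated 0.0140. For dsSpt16 and dsSpt6 r was 0.56 with a covariance of 0.0440 against 0.0139, and for dsSSRP and dsSpt6 0.57 with 0.0389 against 0.0140. With the dsGFP runs split between the knockdowns, r was 0.21, 0.28 and 0.30. The simulation holds counting error only and the split uses 2 technical runs of 1 dsGFP sample, so a shared change was not separated from a deviation of dsGFP itself.

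Among single sites, 3L 9178117 to 9179117 had the largest rise in dsSpt16, a log2 ratio of 1.46 (counting interval 1.27 to 1.66), and also the largest in dsSpt6, 0.91 (0.71 to 1.12). X 21405517 to 21406517 rose by 0.83 in both dsSpt16 (0.73 to 0.92) and dsSSRP (0.73 to 0.92), and 2R 15603133 to 15604133 by 0.74 and 0.85. Values of different knockdowns at a site share its dsGFP count. The largest rise in dsSSRP was at X 15307617 to 15308617, with 0.93 (0.75 to 1.11). Of the 5 highest dsSSRP sites 4 lay on X, which held 55 of all 552 sites. The lowest ratios were -0.97 at 2L 9520450 to 9521450 in dsSpt16, -1.0 at 2R 11668309 to 11669309 in dsSSRP and -0.64 at 2L 107401 to 108401 in dsSpt6.

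In dsSpt16 and dsSSRP the hexasome-sized share changed most at 2R 12915401 to 12916401, where it was 72.7% in dsGFP, 27.3% in dsSpt16, 35.3% in dsSSRP and 47.2% in dsSpt6. The differences in dsSpt16 and dsSSRP were -45.5 points (-62.1 to -28.8) and -37.4 points (-55.1 to -19.8). They share the dsGFP value, which was far above its site median of 46.7%, so they are not independent. At 2L 10298052 to 10299052 the share was 65.3% in dsGFP, 35.1% in dsSpt16 and 42.6% in dsSpt6. The 5 highest changes in dsSpt16 reached only 16.3 to 19.2 points, and the counting interval of 4 of them included 0. The highest values in dsSSRP were 24.3 points at 2R 8922149 to 8923149, and in dsSpt6 24.3 points at 3R 27434263 to 27435263. Most single-site values rest on few fragments, and extremes of a ranking are inflated by counting noise.

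A polymerase that enters a nucleosome could open its site-distal or site-proximal side, so the side of the first nucleosome on which hexasome-sized fragments lie was measured. Hexasome-sized fragments were 49.0% site-distal in S2_total (site bootstrap 47.6 to 50.3), 48.0% in S2_short (46.5 to 49.7), 50.9% in dsGFP, 50.4% in dsSpt16, 49.0% in dsSSRP and 51.0% in dsSpt6. The S2_short interval lay below 50. However, hexasome-sized S2_short density fell from 7.80 times the main-arm mean at the site to 3.18 times at 100 to 200 bp and 2.27 times at 200 to 300 bp. Site-proximal counts can thus include fragments of the peak at the site, and a share below 50 does not show which side of the nucleosome was open. The same limit applies to S2_total, with 4.31 times at the site and 2.89 times at 100 to 200 bp. Control nucleosomes gave 50.2% in S2_short and 50.5% in dsGFP. The difference from nucleosome-sized fragments was -1.74 points in S2_total (site bootstrap -3.19 to -0.26), but 1.36 points in its run 1 alone. In the other 5 libraries the interval of this difference included 0, for example 0.75 points in dsGFP (-3.06 to 4.07). In S2_short it was 3.13 points (-1.63 to 7.98), which rests on only 579 nucleosome-sized fragments. The site-distal percentage in dsSpt16, dsSSRP and dsSpt6 differed from dsGFP by -0.51 points (-2.51 to 1.86), -1.87 points (-3.54 to 0.03) and 0.15 points (-1.70 to 1.97). Further from the site the interval excluded 0 for dsSpt16 at the fourth nucleosome, 2.84 points (0.16 to 5.74), and for dsSpt6 at the second, 1.85 points (0.11 to 3.62), without correction for the number of comparisons, and included 0 in the others. Both flanks of a site were counted together without the strand of transcription, so an asymmetry on the transcribed flank alone would be diluted.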

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

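Length classes, shares, sequence ratios, densities and medians at sites that lay on opposite sides of dsGFP in 2 knockdowns, in both runs, are given here, and these differences were not tested, since each group has 1 sample. The tests of more extensive digestion, of a single X window and of reweighted shares per sequence were chosen after the results were seen, as were the decision to set aside the duplicate test for X and a stricter criterion for digestion, which had first counted as excluded.

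Between the 2 FACT subunits, short fragments changed by -0.850 points of main-arm fragments in dsSpt16 and by 0.50 in dsSSRP, nucleosome-sized fragments by 7.58 and -0.972, and linker-carrying fragments by -2.19 and 1.24. The main-arm hexasome-sized share changed by -8.56 points in dsSpt16, 0.39 in dsSSRP and -2.0 in dsSpt6, and the chromosome 4 ratio was 0.888, 1.11 and 1.02. Nucleosome-sized density at the first nucleosome, scaled by class, had ratios of 1.12 in dsSpt16, 1.38 in dsSSRP and 0.959 in dsSpt6, where scaling to all main-arm fragments gave 1.01. The median log2 ratio at promoter-like sites was -0.025 in dsSpt16, with an interval that includes 0, and 0.11 in dsSSRP. Between dsSpt16 and dsSpt6, short fragments changed by -0.850 and 0.741, partly unwrapped fragments by 3.02 and -0.482, and linker-carrying fragments by -2.19 and 0.0697. The median hexasome-sized share at promoter-like sites changed by -7.61 points in dsSpt16 and 0.574 in dsSpt6, where the interval includes 0. Between dsSSRP and dsSpt6, partly unwrapped fragments changed by 1.32 and -0.482, nucleosome-sized fragments by -0.972 and 1.75, and the median log2 ratio at promoter-like sites was 0.11 and -0.07.

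The hexasome-sized share was lower in dsSpt16 than in dsGFP. More extensive digestion could trim longer fragments to nucleosome size, and nucleosome-sized fragments were higher by 7.58 points while long ones changed by -3.82 and linker-carrying ones by -2.19. Hexasome-sized and short fragments changed by -3.75 and -0.850, where trimming would be expected to add them, so this test cannot decide. For a library-wide difference in the recovery of lengths, the median change at promoter-like sites was within 0.291 points of that at control windows. Against dsGFP reweighted to the dsSpt16 lengths, without the leading windows, the share on 2LHet differed by -2.53 points and on U by -1.85. 2LHet was the furthest sequence, XHet differed by 2.13 the other way, and the dsGFP runs themselves differed by 0.906 on 2LHet. The share on 2LHet also differed by -2.79 in dsSSRP and -3.11 in dsSpt6, each against its own reweighting. Lengths alone thus did not reproduce every sequence, but these departures are not particular to dsSpt16 and cannot decide what caused its drop. Reweighting dsGFP to the main-arm lengths of dsSpt16 removes the difference over all main arms by construction. On 2L, 2R, 3L and 3R, which hold most main-arm fragments, the remaining difference was -0.30 to 0.078. These small values follow from the reweighting and cannot decide the cause of the drop. Recovery, digestion and an effect of Spt16 depletion stay open for the drop with 1 library per group.

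Heterochromatic and unplaced sequence took a larger part of each knockdown library. Identical fragments counted once left a lowest ratio to dsGFP of 1.13, and dsGFP reweighted to the knockdown lengths left 1.18, which argues against duplicates and length composition as the whole cause. A candidate explanation is that a limited set of windows took most of the gain. The top 1% of heterochromatic and unplaced windows held 83.6% of the net gain in dsSpt16, 62.1% in dsSSRP and 69.2% in dsSpt6. Windows that fell cancel part of a net gain, so these percentages are not shares of a whole and do not measure concentration alone. For Het windows of dsSpt16 the value was 272%. The median log2 ratio over heterochromatic and unplaced windows of 1 kb was -0.154 in dsSpt16, 0.09 in dsSSRP and 0.06 in dsSpt6. In dsSpt16 48.3% of U windows and 22.6% of Het windows were above 0, against 21.2% of main-arm windows. In dsSSRP and dsSpt6 71.8% and 71.4% of U windows were above 0, so most U windows that were counted rose there as well. Medians and percentages above 0 cover only windows that passed a minimum of 50 fragments. On U these were 6634 of 10050 windows in dsSpt16, 6800 in dsSSRP and 6811 in dsSpt6. The ratios without the 9 leading windows were 1.18, 1.27 and 1.14. An effect of the depleted chaperones on this chromatin was not tested apart from differences between single libraries.

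The density of X relative to the autosome arms was 1.0 in S2_total and 0.740 in S2_short. Without the window X 21834001 to 21835000 the values were 0.633 and 0.679, so S2_total minus S2_short was -0.0467 and its direction reversed, and this window may be the source of the higher S2_total value. The ratio of S2_total fragments under 120 bp exceeded that of S2_short by 0.234, which met the criterion against size selection written beforehand. Without the window the S2_total ratio of these lengths was 0.678, against 0.679 in S2_short. The excess thus lay in that window, and this test cannot decide on size selection. Counting identical fragments once also reversed S2_total minus S2_short, to -0.0538, which met the criterion for duplicates written before the result was seen. It was set aside afterwards, because the 3084950 S2_total fragments in that window hold 6335 distinct ones in run 1 and 9410 in run 2. The count thus saturates there, and duplicates cannot be told apart from many copies of 1 sequence.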

How the results depend on the processing

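Settings for sites of at least 4 times the arm mean, for leaving out sites or windows, for scaling to all sequences, for scaling densities to all main-arm fragments and for reweighted regional ratios were chosen after the data were seen. Of 229 alternative values for 35 results, 166 stayed within the spread, 56 moved beyond it and 7 changed direction where the main value stood further from no difference than its spread. In all 27 changed sign, and for the other 20 the main value was within its spread of no difference. Where the spread is the SD of the same 2 runs, each run alone is no independent test. Over the runs the hexasome-sized percentage of S2_short minus S2_total ranged from 61.0 to 64.1 points, the site-distal difference in S2_total from -2.35 to 1.36 points (a change of sign), and the X to autosome ratio of S2_short minus S2_total from -0.277 to -0.177. With identical fragments counted once, the main-arm hexasome-sized share differed from dsGFP by -8.07 points in dsSpt16, 0.714 in dsSSRP and -1.95 in dsSpt6, that of heterochromatic and unplaced fragments by -7.88, -2.21 and -2.80, the ratios of heterochromatic and unplaced sequence were 1.14, 1.25 and 1.13, the chromosome 4 ratios 0.879 in dsSpt16 and 1.1 in dsSSRP, and the X to autosome difference changed direction to 0.0538. With narrower length classes, S2_short minus S2_total was 40.003 points, the main-arm share differences were -7.35, 0.0957 and -1.77, the heterochromatic and unplaced ones -8.10, -3.77 and -3.48, and the share at sites in dsSpt16 -6.72. With all sequences, S2_short minus S2_total was 59.0 points, and the share differences were -9.63 in dsSpt16, -1.81 in dsSSRP (a change of direction) and -3.06 in dsSpt6. With a minimum of 100 fragments, median log2 ratios at sites were 0.13 (a change of sign), 0.17 and -0.028 in dsSpt16, dsSSRP and dsSpt6. Scaled to all sequences they were -0.16, -0.063 (a change of direction) and -0.17, a shift set by the larger heterochromatic and unplaced share. Against dsGFP reweighted to the knockdown lengths, the share at sites changed direction to 1.73 points in dsSpt16 and was 2.5 points in dsSpt6, and the heterochromatic and unplaced ratios were 1.21, 1.3 and 1.18. That reweighting removes a library-wide length difference by construction. Dyads called in the low-salt libraries gave a site-distal difference of -2.80 points in S2_short, a change of sign. Without the 9 leading windows outside the main arms, the heterochromatic and unplaced ratios were 1.18, 1.27 and 1.14 and the share differences -10.0, -3.32 and -3.30. Without the X window the X to autosome difference changed direction to 0.0467. With sites at least 4 times the arm mean, the short ratio in dsSpt16 was 1.6, the nucleosome-sized ratios at the first nucleosome 1.01 in dsSpt16, 1.24 in dsSSRP and 0.893 in dsSpt6, the hexasome-sized ratios 1.2 in dsSSRP and 1.01 in dsSpt6, and the median log2 ratio in dsSSRP 0.039. Without the 10% of sites with the most fragments, the nucleosome-sized ratios were 0.972 (a change of direction), 1.21 and 0.872, and the hexasome-sized ratios 1.0, 1.15 and 1.01. Scaled to all main-arm fragments, the hexasome-sized ratios at the first nucleosome were 0.960 in dsSpt16 (a change of direction) and 1.03 in dsSpt6, and the nucleosome-sized ones 1.36 in dsSpt16 and 1.01 in dsSpt6 (a change of sign), which follows from class sizes that differ between libraries. Apart from the changes that construction explains, the cause was not tested. Thinning, no minimum, midpoints 10 to 40 bp from the dyad and S2 run 1 ends shortened by 1 bp moved no result beyond its spread. A smaller number of sites was not run, since only 552 passed, and scaling to the median ratio sets the medians to 0. At single sites the hexasome-sized share differed between the dsGFP runs with an SD of 11.9 points, and how much of it depth sets was not tested.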

Other observations

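These values were all singled out after the data were seen. The S2 and low-salt libraries differed in a few sequences beyond the comparisons above, and the labels give them different cell stocks as well as different extractions. The 1 kb window U 2606001 to 2607000 held 0.288% of S2_total and 0.332% of S2_short fragments, but 0.000537% of dsGFP, 0.000420% of dsSpt16, 0.000778% of dsSSRP and 0.000567% of dsSpt6 fragments. Fragment density on 3L relative to the mean of 2L, 2R, 3L and 3R was 1.03 in S2_total and 1.03 in S2_short, against 0.867 in dsGFP, 0.876 in dsSpt16, 0.880 in dsSSRP and 0.872 in dsSpt6. On 2L the order was opposite, with 1.03 in S2_total and 1.12 in dsGFP. The median 1 kb window of chromosome 4 had 0.951 times the autosome value in S2_total, 0.805 times in dsGFP, 0.649 times in dsSpt16, 0.860 times in dsSSRP and 0.803 times in dsSpt6.

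The window U 7316001 to 7317000 held 5.98% of all S2_short fragments, with ends mostly between 7316202 and 7316311, and 64.8% of them were short. In S2_total its share differed between runs, 4.69% in run 1 and 0.233% in run 2, and in S2_short it was 10.6% and 5.20%. The window U 9151001 to 9152000 held 0.266% of S2_short run 1 and 4.32% of run 2. In dsGFP the same window held 0.170% of run 1 and 0.163% of run 2.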
